A study of Oreochromis niloticus with 8 samples.

How the data were processed

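RNA of spleen lymphocytes was taken from 8 samples, 4 of a normal group (ctrl) and 4 of a behavioral fever group (fever), on day 4 after infection. Per the labels' protocols, RNA was extracted with Trizol, and libraries were made from 1.3 ug of total RNA with a SMARTER mRNA kit. The sources used here do not state whether that kit kept the strand, so reads of a gene and of an overlapping antisense gene may not be separated. One table of the whole series was used. Per the file headers it holds an expected count and an FPKM value for each gene and sample, with a gene symbol, a description, and KEGG and GO annotation. The deposited expected counts are not normalized, and 89.1% of them were whole numbers within 1e-08. They were rounded to whole numbers before testing. The deposited FPKM values are fragments relative to transcript length and to the library's fragments, and they served only as an alternative. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10, which are mouse builds and cannot be the source of tilapia gene identifiers, so no build and no coordinates are given. All per-sample columns of the table were used.

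The table holds 28305 genes, 26839 with ENSONIG identifiers and 1466 with MSTRG identifiers of assembled transcripts. A symbol is given for 16467 genes, and 7554 have neither a symbol nor a description. In 5131 genes all 8 counts were 0. Of 15353 genes with an NCBI gene number, 14656 were matched to the RefSeq annotation of the assembly O_niloticus_UMD_NMBU, which was used for names only. Symbols and descriptions are those of the deposited table and some contradict each other, such as klf1 described as zinc finger protein 143 and tgm5l described as elastase-1.

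The groups, main tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM normalization, its default filter on low counts, robust estimation and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, over all 14217 tested genes and, for each gene list, over the list alone. TMM factors were 1.036, 0.981, 1.242 and 1.168 in ctrl-1 to ctrl-4 and 0.84, 0.956, 0.9 and 0.938 in fever-1 to fever-4. CPM in the text is a count relative to the library total, scaled by these factors, while shares are percentages of unscaled library totals. The common biological coefficient of variation was 0.512.

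Of 36 gene lists, 35 had tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), which compares a list with all other genes. The list of mitochondrially encoded genes matched 0 genes. With an estimated correlation 0 of the 35 lists passed (smallest adjusted p 0.203), against 11 with the preset one, and 3 lists passed fry, which tests whether the genes of a list move on balance one way. With fry these were the endoplasmic reticulum list (adjusted p = 0.0227), the cholesterol and fatty acid list (0.0391) and the plasma cell list (0.0391). Genes joined a list by symbol, by fish copy suffix or by a phrase in the description. A metacaspase, trypsin domain containing 1 and immunoglobulin mu DNA binding protein 2 entered lists through their wording alone, and leaving them out kept all 11 calls. gfi1b, a symbol of the erythroid list, also joined the neutrophil list as a suffixed copy of gfi1 and was kept there.

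The named genes were, by rule, those with the largest changes past the threshold over all genes (which none passed), up to 4 called members of each list, a set of sentinel genes reported whether or not they changed, and, where fewer than 10 genes passed in a direction, the 5 with the smallest p. Sentinels without a matching symbol were rbm3, casp8, fas, cd3e, cd4, cd8a, ifng, il2 and ighm, and gzmb, 3 copies of hspa5 and a second mcl1b gene were below the filter. Some sentinels of the set are not reported here. Other genes named as examples of lists, the measure of immunoglobulin heavy chain counts (KEGG orthology of the heavy chain, 111 genes, 103 without a description), light chain and hemoglobin shares and the camera tests of KEGG pathways were chosen after the data were seen. Shares of counts were compared with exact permutation tests, two-sided, in which 4 against 4 gives no p below 0.0286.

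Precision was tested on simulated counts for this comparison, with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. With the dispersions estimated from these libraries, edgeR recovered 0% of the 2-fold and 4% of the 4-fold genes (13843 genes). With a dispersion of 0.05 it recovered 69% and 95% (14017 genes, 3 unchanged genes called). Within groups, the chi-square per degree of freedom between libraries was 32.4 to 219, so no library repeated another of its group. Pairs of a ctrl and a fever library were not tested in this way.

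Alternatives for gene tests were median-of-ratios, upper-quartile and total-count scaling, no filter and a stricter filter (at least 10 counts in at least 4 libraries and a mean CPM of at least 5), DESeq2 1.42.0, limma-voom, edgeR without robust estimation, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a minimum of 1 in 4 libraries, log2(FPKM + 1) without a minimum, and leaving out each library in turn. Alternatives for lists were the other set tests, scalings and symbol matches alone. Leaving out ctrl-3 and fever-1 together, sample quality weights, RefSeq symbols and list-alone counts under each setting were chosen after seeing the data. Fisher tests of KEGG pathways (10 to 300 tested members) were planned on edgeR calls and were also run on DESeq2 calls, with and without heavy chain genes, since edgeR made none. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.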

Results

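Spleen lymphocytes of the Nile tilapia (Oreochromis niloticus), a cichlid fish whose body temperature follows the water, were profiled by RNA sequencing on day 4 after infection. Behavioral fever is the movement of an infected ectotherm towards warmth, and the series asks how it bears on T cell apoptosis and antimicrobial immunity. The labels name 4 libraries of a behavioral fever group (fever-1 to fever-4) and 4 of a normal group (ctrl-1 to ctrl-4). The pathogen and the water temperatures are not given in the sources used here. Nothing in the labels says that the 4 samples of a group came from separate fish, so p-values measure only the spread between these samples. Within groups, the chi-square per degree of freedom between libraries was 32.4 to 219, which argues against repeated sequencing of the same library within a group. Whether each sample is a separate fish stays open. Total counts were 10257088, 13621568, 12725267 and 14810001 in ctrl-1 to ctrl-4, and 13845601, 11659929, 12079454 and 11676854 in fever-1 to fever-4. Of 28305 genes in the table, 14217 had enough counts to be tested, and the median standard error of a log2 change was 0.37.

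The second principal component of log2 CPM separated the groups, with ctrl libraries between 18.9 and 65.7 and fever libraries between -55.1 and -22.1. On the first component, ctrl-3 at 67.2 and fever-1 at 111.1 lay apart from the other libraries, which ranged from -57.6 to 9.3. On genes ranked in the remaining libraries, with the ctrl mean at 0 and the fever mean at 1, fever-1 lay at 0.24 to 0.34, within the range of the ctrl libraries (-0.07 to 0.43), and the other fever libraries lay at 0.63 to 0.85.

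**Figure D1:**
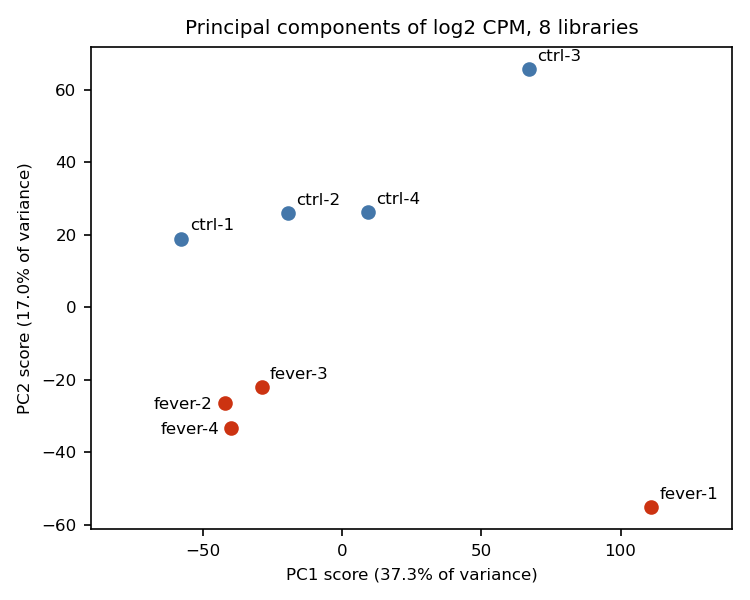
Principal component scores of log2 CPM for the 8 libraries, with PC1 (37.3% of the variance) on the horizontal axis and PC2 (17% of the variance) on the vertical axis, ctrl in blue and fever in red. All 4 ctrl libraries have positive PC2 scores and all 4 fever libraries negative ones, while fever-1 (111.1) and ctrl-3 (67.2) have the highest PC1 scores.

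The comparison of fever with ctrl asks which transcripts of spleen lymphocytes differ between fish of the behavioral fever group and of the normal group on day 4. Genes for folding and export of secreted proteins in the endoplasmic reticulum, and plasma cell marker genes, were higher in the fever libraries as groups, with median changes of 1.71-fold over 29 genes and 2.04-fold over 8 genes, but neither list passed camera with an estimated correlation (adjusted p = 0.203 and 0.276). Transcripts of immunoglobulin heavy chain genes made up 3.15% ± 0.864 of all counts in fever and 0.784% ± 0.521 in ctrl (SD, n = 4), but a single gene held 90.6% of these counts, and without it the log2 difference turned from 2.19 to -1.03. Genes for ribosomal proteins and respiratory chain subunits were higher by smaller amounts, with medians of 1.32-fold and 1.26-fold, and cell cycle genes had a median of 0.705-fold, and these lists did not pass with an estimated correlation either (adjusted p = 0.708, 0.854 and 0.777). With library totals as the only scaling, the ribosomal and respiratory chain medians moved from 0.40 to 0.14 and from 0.33 to 0.01 on the log2 scale. With its preset correlation camera passed each of the gene lists named above. Lists of pro-apoptotic and anti-apoptotic genes, cytosolic heat shock proteins and cytotoxic effectors did not pass it (adjusted p = 0.144, 0.479, 0.437 and 0.479).

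Single genes did not reach the threshold in the edgeR test. It called 0 of 14217 genes (smallest adjusted p 0.355), with 1185 at an unadjusted p under 0.05, of which 795 had positive and 390 negative changes. limma-voom also called 0, with 1039 at an unadjusted p under 0.05, and DESeq2 called 195 of 16785 genes, 169 higher and 26 lower, of which 161 differed at least 2-fold. Without fever-1, edgeR called 18 genes, all higher and all at least 2-fold, and 17 of them were among the DESeq2 calls. In 818 genes (5.75%) the 4 fever values all lay above (554 genes) or below (264 genes) the 4 ctrl values. By chance the average is 2.86% over all splits of the 8 libraries into 4 and 4, but single splits gave 67 to 1600 genes.

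The genes with the smallest p in each direction are given as values. cited4a (ENSONIG00000007568), a transcriptional co-regulator, measured 16.7 ± 2.15 CPM in ctrl and 43.4 ± 2.78 CPM in fever (SD, n = 4), a log2 change of 1.38 ± 0.18 (SE; edgeR adjusted p = 0.355). txndc15 (ENSONIG00000033072), a protein with a thioredoxin domain, measured 21.1 ± 3.32 and 51.0 ± 9.42 CPM. ENSONIG00000037564, ENSONIG00000031379 and ENSONIG00000029127, which carry no name or description in the table, had log2 changes of 3.41, 3.36 and 2.64. In the other direction, exoc3l1 (ENSONIG00000010884), related to subunits of the exocyst, measured 2.00 ± 0.761 CPM in ctrl and 0.247 ± 0.0422 CPM in fever. sfi1 (ENSONIG00000004256), a centrin-binding protein, measured 21.8 ± 6.60 and 8.76 ± 1.49 CPM. The uncharacterized ENSONIG00000002339, xirp2a (ENSONIG00000011839) and lzts1 (ENSONIG00000011797) had log2 changes of -1.65, -3.65 and -1.53. These 10 genes had edgeR adjusted p values of 0.355 to 0.394.

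**Figure D2:**
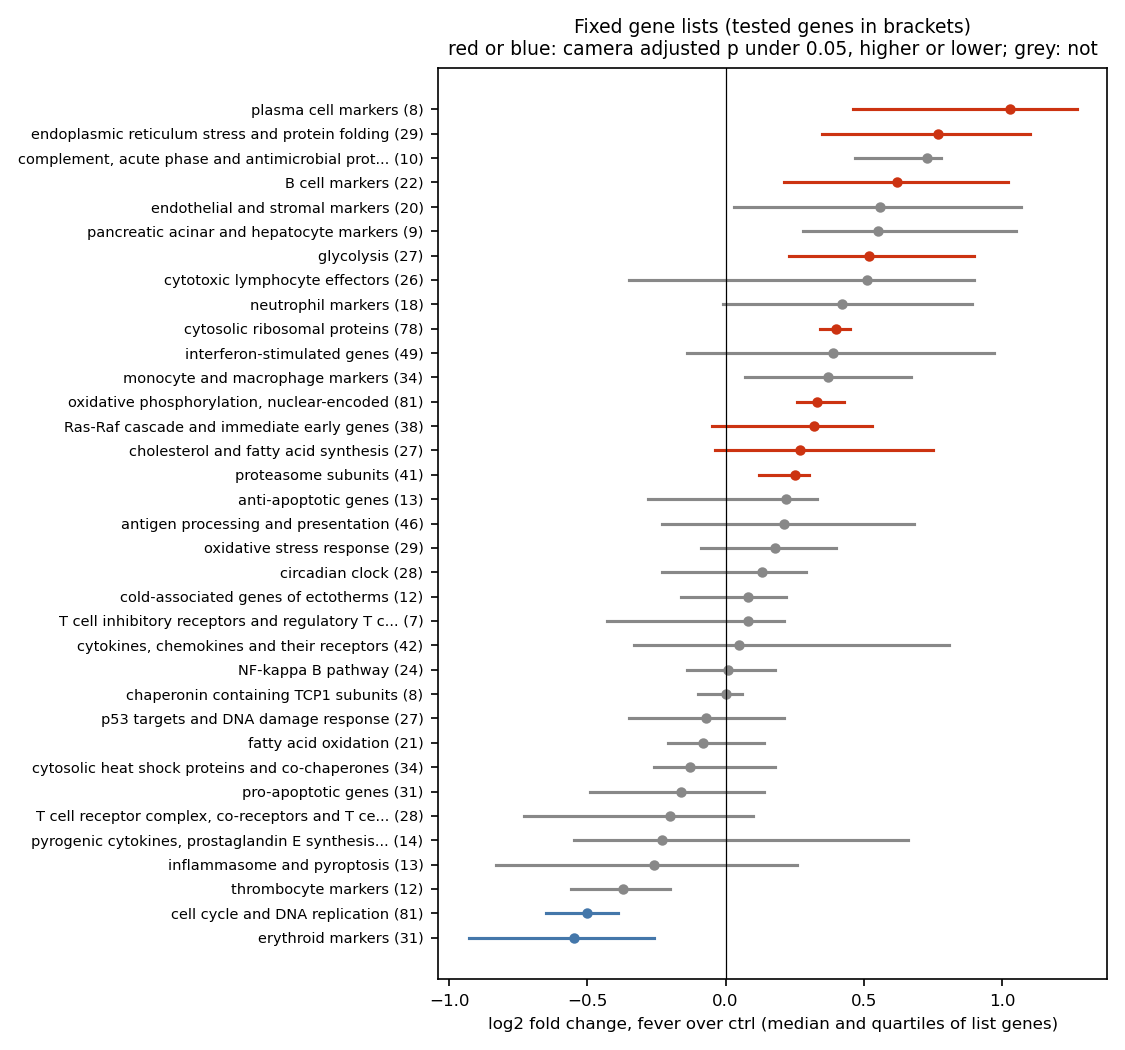
Median (point) and quartiles (line) of the log2 fold change of fever over ctrl for the tested genes of 35 gene lists, with the number of genes in brackets, in red or blue where camera gave an adjusted p under 0.05 with its preset correlation. Medians run from -0.55 (erythroid markers) to 1.03 (plasma cell markers). Scaled by library totals alone, the medians of the proteasome list (0.25 to -0.08) and of the cholesterol and fatty acid list (0.27 to -0.04) change sign, as do those of other lists near 0.

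Genes of endoplasmic reticulum stress and protein folding were higher in fever as a group. Of 29 tested genes, 24 had positive changes, 14 rose and 0 fell with edgeR p-values adjusted over the list alone, 16 had an unadjusted p under 0.05, and 0 passed over all genes tested. xbp1 (ENSONIG00000010547), a transcription factor of the unfolded protein response that secretory cells need, rose from 330 ± 65.1 to 798.6 ± 210 CPM (SD, n = 4). hsp90b1 (ENSONIG00000008526), a chaperone of the endoplasmic reticulum, rose 2.47-fold from 772 ± 229 to 1905 ± 537 CPM, and pdia4 (ENSONIG00000014419), a disulfide isomerase, rose 3.06-fold. creld2 (ENSONIG00000009787) rose 4.45-fold and manf (ENSONIG00000018556) rose 1.81-fold, from 104 ± 6.09 to 188 ± 13.4 CPM. The other 9 that rose were dnajc3a, dnajc3b, dnajb11, dnajb9, syvn1, pdia6, herpud1, ern1 and sdf2l1, with changes of 1.61-fold to 2.16-fold. hspa5 (BiP, ENSONIG00000039112), the main chaperone of this compartment, measured 1030 ± 101 and 1525 ± 569 CPM, and a second hspa5 gene (ENSONIG00000033493) measured 20.4 ± 8.34 and 8.78 ± 8.02 CPM. ddit3, a transcription factor of prolonged stress, had a fold change of 0.898 and atf4b one of 0.968, with edgeR adjusted p values of 0.965 and 0.976. The list passed camera (adjusted p = 2.94e-12), but not with an estimated correlation (adjusted p = 0.203 with an estimated correlation), and fry gave an adjusted p of 0.0227. Adjusted over the list alone, 15 genes passed with DESeq2 and 14 with limma-voom, but 0 passed with library totals as the only scaling (smallest adjusted p 0.0555) or on FPKM (smallest adjusted p 0.0803), where the medians were 0.50 and 0.43 on the log2 scale instead of 0.77. The count was 5 without ctrl-2, 8 without ctrl-3, 5 without fever-3 and 7 without fever-4.

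Markers of plasma cells, the antibody-secreting end stage of B cells, were also higher as a group. Of 8 tested genes 7 had positive changes, 5 had an unadjusted p under 0.05, and 3 rose with p adjusted over the list alone, beside 0 over all genes tested with edgeR. The first was xbp1, which is also in the endoplasmic reticulum list, so the 2 lists are not independent. The others were ssr4 (ENSONIG00000036077), a subunit of the translocon-associated complex, which rose from 186 ± 41.5 to 490.4 ± 84.5 CPM, and fkbp11 (ENSONIG00000031092), which rose from 23.4 ± 8.59 to 55.6 ± 9.90 CPM (SD, n = 4). prdm1a (Blimp-1, ENSONIG00000006687) measured 90.9 ± 26.3 and 220 ± 205 CPM, with 528 CPM in fever-1, and irf4a (ENSONIG00000009637) measured 15.3 ± 4.65 and 8.91 ± 5.55 CPM. The more abundant irf4b (ENSONIG00000006398) measured 163.1 ± 80.7 and 163.8 ± 78.7 CPM. The listed jchain, tnfrsf17, sdc1 and mzb1 had no tested gene. camera gave an adjusted p of 0.000664 (adjusted p = 0.276 with an estimated correlation).

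The heavy chain share of all counts, a measure chosen after the data were seen, was 0.814, 0.470, 0.345 and 1.51% in ctrl-1 to ctrl-4 and 1.97, 4.05, 3.25 and 3.33% in fever-1 to fever-4. The fold of means was 4.02 and the exact permutation p (two-sided) was 0.0286, the smallest that 4 against 4 allows. Of 40 tested heavy chain genes, 37 had positive changes, with a median log2 change of 1.62. A single gene, ENSONIG00000035343, held 90.6% of these counts and measured 5104 ± 4450 CPM in ctrl and 32960 ± 6950 CPM in fever (SD, n = 4). Without it the log2 difference turned from 2.19 to -1.03 (exact permutation p = 0.229), and ENSONIG00000010955, the next in abundance, measured 1724 ± 424 and 416 ± 276 CPM. With both left out the log2 difference was 1.45 (exact permutation p = 0.114), and without fever-1, fever-2, fever-3 or fever-4 in turn it was 2.40, 2.06, 2.16 and 2.15, with groups that still did not overlap and an exact permutation p of 0.0571 for each. Genes described as immunoglobulin light chains took 0.0427% ± 0.0108 of counts in ctrl and 0.149% ± 0.0796 in fever (SD, n = 4; exact permutation p = 0.0857). Of 15 tested light chain genes, 9 had positive and 6 negative changes, 2 higher and 1 lower at an unadjusted p under 0.05, with a median log2 change of 0.06. Among them ENSONIG00000030109 measured 68.1 ± 15.4 and 736.5 ± 531 CPM, and ENSONIG00000041748 measured 155 ± 45.3 and 743 ± 315 CPM. Heavy and light chain genes are families of near-identical copies, so the division of counts among their members is uncertain.

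**Figure D3:**
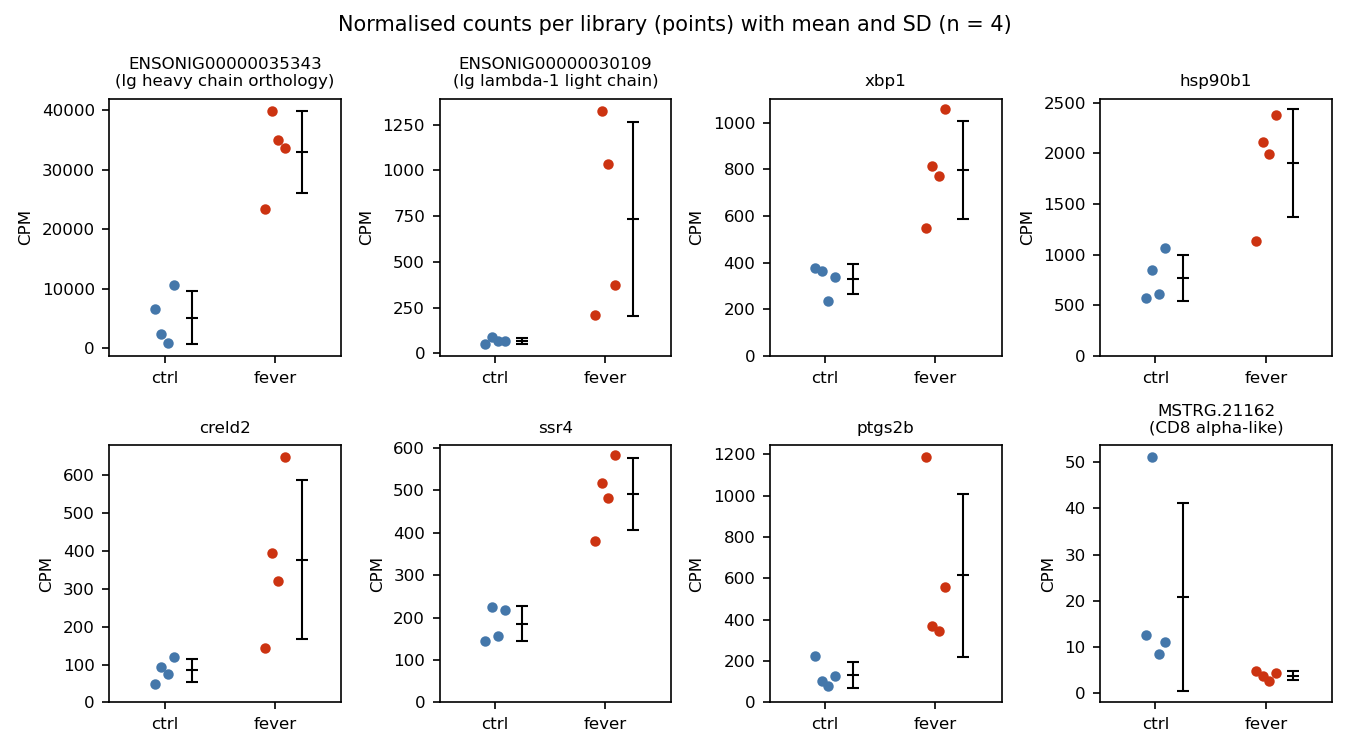
Normalised counts (CPM, linear axes from near 0) of 8 genes in each ctrl library (blue points) and fever library (red points), with mean and SD (black, n = 4). In all panels the groups do not overlap: ENSONIG00000035343 lies at 777 to 10678 CPM in ctrl and 23312 to 39828 CPM in fever, and MSTRG.21162 at 8.44 to 51.1 CPM in ctrl and 2.58 to 4.75 CPM in fever. The genes were chosen after their values were seen.

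B cell markers were higher as a group in camera (22 genes, 18 with positive changes, 3 at an unadjusted p under 0.05; median 1.53-fold; adjusted p = 0.00575). The call was lost when the correlation was estimated (adjusted p = 0.679 with an estimated correlation). cd79a (ENSONIG00000011435), part of the B cell receptor, measured 44.1 ± 24.6 CPM in ctrl and 185 ± 115 CPM in fever (SD, n = 4), with 23.2 CPM in fever-1. syk (ENSONIG00000011225), a kinase downstream of that receptor, measured 223 ± 28.4 and 329 ± 67.7 CPM. In the list, 3 genes also carry the heavy chain orthology. The erythroid list, which marks red blood cells, was lower in the same comparison (31 genes, 26 with negative changes, 4 at an unadjusted p under 0.05; median 0.683-fold; camera adjusted p = 0.00575, and adjusted p = 0.854 with an estimated correlation). alas2 (ENSONIG00000002184), of heme synthesis, measured 1029 ± 957 and 493 ± 300 CPM, and slc4a1a (ENSONIG00000000778), the band 3 anion exchanger, 509 ± 432 and 182 ± 43.8 CPM. Hemoglobin transcripts took 3.84% ± 3.02 of counts in ctrl and 2.54% ± 0.745 in fever (SD, n = 4; exact permutation p = 0.857). The erythroid call was lost without ctrl-2 (adjusted p = 0.0797), ctrl-4 (0.23) or fever-3 (0.0574), and the median of -0.55 on the log2 scale was -0.92 under library totals and -0.73 on FPKM, while that of B cell markers moved from 0.62 to 0.39 and 0.32.

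Lists of protein synthesis and energy metabolism were higher as groups, with small positive changes in most members. In the lists of this paragraph 0 genes passed with p adjusted over the list alone. Of 78 cytosolic ribosomal protein genes, 76 had positive changes and 13 an unadjusted p under 0.05 (camera adjusted p = 5.73e-17; adjusted p = 0.708 with an estimated correlation), and rpl15 (ENSONIG00000010307) measured 2290 ± 405 and 3390 ± 508 CPM. Of 81 nuclear-encoded genes of oxidative phosphorylation, 79 had positive changes and 11 an unadjusted p under 0.05 (camera adjusted p = 4.68e-09; adjusted p = 0.854 with an estimated correlation), and ndufa2 (ENSONIG00000041745), of respiratory complex I, measured 32.9 ± 4.95 and 52.95 ± 1.48 CPM. With library totals as the only scaling the median of all tested genes moved from 0.008 to -0.27, and the medians of these lists moved with it. Of 41 proteasome genes, 37 had positive changes and 0 an unadjusted p under 0.05 in edgeR (adjusted p = 0.023; adjusted p = 0.855 with an estimated correlation), with a median of 0.25 that turned to -0.08 under library totals and -0.04 on FPKM. psmc3 (ENSONIG00000017062), an ATPase of the proteasome, measured 155 ± 36.0 and 212 ± 45.1 CPM. The proteasome call was lost without ctrl-1 (adjusted p = 0.951), fever-1 (0.39), fever-2 (0.062) or fever-3 (0.308). Of 27 genes of cholesterol and fatty acid synthesis, 19 had positive changes and 4 an unadjusted p under 0.05 (adjusted p = 0.0186; adjusted p = 0.276 with an estimated correlation), with a median of 0.27 that turned to -0.04 under library totals. srebf1 (ENSONIG00000002304), a regulator of lipid synthesis, measured 58.9 ± 25.7 and 111 ± 57.6 CPM, and the cholesterol call was lost without fever-1 (adjusted p = 0.106).

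Glycolysis genes were higher as a group over all 8 libraries, but not without fever-1. Of 27 genes 25 had positive changes and 1 an unadjusted p under 0.05 (median 1.43-fold; camera adjusted p = 0.023; adjusted p = 0.855 with an estimated correlation). The median was 0.52 on the log2 scale, 0.17 under library totals and 0.04 on FPKM. The direction turned without fever-1 (adjusted p = 0.592), and the call was also lost without ctrl-1 (adjusted p = 0.262). gapdhs (ENSONIG00000037136), a glyceraldehyde-3-phosphate dehydrogenase, measured 12289 CPM in fever-1 and 2127 to 2842 CPM in the other fever libraries. slc2a3b (ENSONIG00000012832), a glucose transporter, measured 1262 CPM in fever-1 and 136 to 254 CPM in the others. Genes of the Ras-Raf cascade and immediate early genes passed with 26 of 38 changes positive and 1 at an unadjusted p under 0.05 in each direction (median 1.25-fold; adjusted p = 0.0332; adjusted p = 0.855 with an estimated correlation). JUND (ENSONIG00000021047), a subunit of the AP-1 factor, measured 36.8 ± 8.06 and 87.8 ± 51.1 CPM. The median of this list moved from 0.32 to 0.09 under library totals, and its call was lost without ctrl-3 (adjusted p = 0.182), ctrl-4 (0.439) or fever-4 (0.0603).

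Genes of the cell cycle and DNA replication were lower as a group. Of 81 genes, 77 had negative changes and 8 an unadjusted p under 0.05, with a median of 0.705-fold (camera adjusted p = 2.45e-13; adjusted p = 0.777 with an estimated correlation). On the log2 scale the median was -0.50, and it was -0.82 under library totals and -0.74 on FPKM. mki67 (ENSONIG00000019914), a proliferation marker, measured 355 ± 93.2 CPM in ctrl and 204 ± 65.0 CPM in fever (SD, n = 4), and pcna (ENSONIG00000041691), the DNA polymerase clamp, measured 510.3 ± 92.7 and 391 ± 144 CPM. CDC25B (ENSONIG00000012295), a phosphatase that starts mitosis, measured 131 ± 10.3 and 87.8 ± 9.97 CPM, with no overlap between the groups. hmmr and tk1 had log2 changes of -1.20 and -1.12. The centred list mean was lowest in fever-4 (-0.922) and also negative in ctrl-1 (-0.414), while fever-3 had a positive one (0.135).

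Lists of T cell and apoptosis genes did not pass camera in either direction. The list of the T cell receptor complex, co-receptors and T cell identity had 19 of 28 changes negative and 2 at an unadjusted p under 0.05, with a median log2 change of -0.20 (camera adjusted p = 0.0656), which was -0.41 under library totals and -0.50 on FPKM. It passed as lower without ctrl-3 (adjusted p = 0.00269), ctrl-4 (0.0101), fever-2 (0.0163), fever-3 (0.0375) or fever-4 (0.00995). MSTRG.21162 and MSTRG.21161, both described as CD8 alpha chain-like and thus part of the co-receptor of cytotoxic T cells, had log2 changes of -2.43 and -1.90 (edgeR adjusted p = 0.404 for both). ENSONIG00000039771, described as CD3e, a chain of the T cell receptor complex, which the list's symbols and phrases did not match, measured 19.9 ± 20.2 and 2.23 ± 1.76 CPM. zap70 (ENSONIG00000010079), a T cell receptor kinase, measured 321 ± 148 and 284 ± 147 CPM, and cd4-1 (ENSONIG00000013024) measured 78.8 ± 64.9 and 77.4 ± 40.2 CPM. The centred mean of the T cell list was -1.69 in fever-1 and 0.212 to 0.406 in the other fever libraries.

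Pro-apoptotic genes had 19 of 31 changes negative, 1 in each direction at an unadjusted p under 0.05, and a median log2 change of -0.16 (camera adjusted p = 0.144), which was -0.44 under library totals and -0.42 on FPKM. Anti-apoptotic genes had 9 of 13 positive and a median of 0.22 that turned to -0.02 under library totals (adjusted p = 0.479). Among executioner caspases, casp3a (ENSONIG00000034753) measured 39.6 ± 3.91 CPM in ctrl and 35.4 ± 8.87 CPM in fever, and casp3b (ENSONIG00000030573) 16.0 ± 3.90 and 21.4 ± 22.8 CPM, with 55.5 CPM in fever-1 (SD, n = 4). casp9 (ENSONIG00000006629), an initiator caspase, measured 65.6 ± 7.83 and 74.6 ± 32.8 CPM, and ENSONIG00000015679, described as caspase-8, 42.0 ± 8.61 and 39.3 ± 5.53 CPM. The mitochondrial effector baxa (ENSONIG00000041423) measured 97.3 ± 14.3 and 88.1 ± 11.1 CPM. The survival genes bcl2b (ENSONIG00000017372) and mcl1b (ENSONIG00000006658) measured 3.47 ± 0.678 and 2.56 ± 1.19 CPM, and 689 ± 377 and 773 ± 109 CPM. bnip3, ripk1l and faslg had log2 changes of 0.84, -0.84 and 1.28 with edgeR adjusted p values of 0.595, 0.431 and 0.647. The p53 and DNA damage list (27 genes, 3 lower and 0 higher at an unadjusted p under 0.05 in edgeR) had a median of -0.07 (adjusted p = 0.216), and the inflammasome and pyroptosis list (13 genes) a median of -0.26 (adjusted p = 0.393), and these were -0.35 and -0.56 under library totals.

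Cytotoxic lymphocyte effectors had 17 of 26 changes positive, 1 at an unadjusted p under 0.05, and a median log2 change of 0.51 that turned to -0.11 on FPKM (camera adjusted p = 0.479). ctsc (ENSONIG00000005125), the protease that activates granzymes, measured 188 ± 45.3 and 375 ± 115 CPM, and prf1.3 (ENSONIG00000009313), a perforin, measured 5.79 ± 3.81 and 10.8 ± 7.47 CPM. ENSONIG00000038802, described as granzyme K-like, measured 145 CPM in fever-3 and 0.086 to 4.48 CPM in the other fever libraries. tbx21 (ENSONIG00000018223), the T-bet factor of cytotoxic and type 1 helper cells, measured 77.7 ± 32.4 and 85.6 ± 25.2 CPM. Inhibitory receptors and regulatory T cell genes (7 genes) had a median of 0.08 that turned to -0.18 under library totals, and a negative mean and test direction (adjusted p = 0.653).

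Cytosolic heat shock proteins and co-chaperones had 23 of 34 changes negative and a median log2 change of -0.13, with a positive mean of 0.13 (camera adjusted p = 0.437), and the median was -0.47 under library totals and -0.41 on FPKM. The abundant HSPA8 (ENSONIG00000004759) measured 5133 ± 633 CPM in ctrl and 6205 ± 1240 CPM in fever (SD, n = 4), and hsp90ab1 (ENSONIG00000005936) measured 5306 ± 740 and 5328 ± 1060 CPM. hspa8b (ENSONIG00000011144) measured 36.8 ± 21.2 and 26.4 ± 6.67 CPM. The inducible hsp90aa1.1 (ENSONIG00000000819) measured 185 CPM in fever-1 and 23.9 to 28.5 CPM in the other fever libraries, and its log2 change of 1.35 was -0.04 without fever-1. An hsp70 gene (MSTRG.19369) measured 596 CPM in fever-1 and 19.7 to 40.3 CPM in the others. Cold-associated genes (12 genes) had a median of 0.08 that turned to -0.21 under library totals (adjusted p = 0.653), and cirbpb (ENSONIG00000010169), a cold-inducible RNA-binding protein, measured 1205 ± 147 and 1354 ± 177 CPM. In the list of pyrogenic cytokines, prostaglandin E synthesis and thermosensitive channels (14 genes; median -0.23, or -0.47 under library totals; adjusted p = 0.7), 1 gene rose with p adjusted over the list alone and 0 over all genes tested with edgeR. It was ptgs2b (ENSONIG00000010015), a cyclooxygenase-2 of prostaglandin synthesis, with 132 ± 63.8 CPM in ctrl and 614 ± 393 CPM in fever, while ptgs1 (ENSONIG00000010712) measured 24.2 ± 8.00 and 12.5 ± 3.91 CPM. Chaperonin subunits (8 genes) had a median of 0.00 that was -0.30 under library totals (adjusted p = 0.872).

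Innate immune lists did not pass camera. The list of complement, acute phase and antimicrobial proteins had 9 of 10 changes positive and 1 at an unadjusted p under 0.05, with a median of 1.66-fold (adjusted p = 0.0575). Its median was 0.73 on the log2 scale and 0.03 on FPKM. The list passed as higher with library totals as the only scaling (adjusted p = 0.00704), with upper-quartile scaling (0.0343), with the replicate number as a block (0.0231) and without ctrl-3 and fever-1 (0.0245), and leaving out each of the 8 libraries in turn gave adjusted p values of 0.00602 (without fever-1) to 0.0497 (without fever-3), all as higher. ENSONIG00000039512, described as hepcidin, an iron-regulating antimicrobial peptide, measured 43.7 ± 17.9 CPM in ctrl and 127 ± 42.9 CPM in fever (SD, n = 4). Interferon-stimulated genes had 35 of 49 changes positive, 4 higher and 3 lower at an unadjusted p under 0.05, and a median of 1.31-fold (adjusted p = 0.335), and passed as higher without fever-4 (adjusted p = 0.00548), with library totals as the only scaling (0.027) and with symbol matches alone (0.0203), while the median moved from 0.39 on the log2 scale to 0.03 on FPKM. isg15 (ENSONIG00000028326) measured 4.65 ± 2.76 and 15.4 ± 9.28 CPM, and stat1a (ENSONIG00000012194) 311 ± 109 and 644 ± 293 CPM. The smallest p values of the list belonged to 3 genes with negative changes, ENSONIG00000019137, described as an interferon-induced protein with tetratricopeptide repeats (85.7 ± 27.3 and 36.4 ± 14.1 CPM), ENSONIG00000038154, an interferon-induced very large GTPase (7.00 ± 5.26 and 2.20 ± 0.0951 CPM), and ENSONIG00000038474, an interferon-induced protein 44 (21.7 ± 31.0 and 0.720 ± 1.38 CPM, with 66.9 CPM in ctrl-2). Cytokines, chemokines and their receptors (42 genes) had a median log2 change of 0.05 (adjusted p = 0.393), the NF-kappa B pathway (24 genes) 0.01 (adjusted p = 0.645), and antigen processing and presentation (46 genes) 0.21 (adjusted p = 0.479), and these medians turned to -0.17, -0.22 and -0.08 under library totals.

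Markers of other cell types and the remaining metabolic lists did not pass camera. Monocyte and macrophage markers had 26 of 34 changes positive, 2 at an unadjusted p under 0.05, and a median of 1.29-fold (adjusted p = 0.216), passing without ctrl-4 (0.0413) or fever-3 (0.039), and csf1ra (ENSONIG00000013065), a receptor of this lineage, measured 57.7 ± 25.7 and 60.1 ± 21.4 CPM. Neutrophil markers had 13 of 18 positive, 2 higher and 1 lower at an unadjusted p under 0.05, and a median of 1.33-fold (adjusted p = 0.301), passing without fever-3 (0.0395). The lower gene was gfi1b, a symbol of the erythroid list that joined as a suffixed copy of gfi1. mpx (ENSONIG00000003558), a granulocyte peroxidase, measured 2019 CPM in fever-1, 1618 CPM in ctrl-3 and 91.3 to 314 CPM in the other fever libraries. Thrombocyte markers (12 genes) had a median of 0.776-fold (adjusted p = 0.216), passing as lower without ctrl-3 (0.0307), and endothelial and stromal markers (20 genes) one of 0.56 on the log2 scale that was -0.14 on FPKM (adjusted p = 0.425). Pancreatic acinar and hepatocyte markers (9 genes) had a median of 1.47-fold (adjusted p = 0.208), passing as higher with library totals as the only scaling (0.0393). Oxidative stress genes had 20 of 29 positive and a median of 0.18 that turned to -0.14 under library totals (adjusted p = 0.584). In that list 1 gene, prdx4 (ENSONIG00000005145), a peroxiredoxin of the endoplasmic reticulum, rose with p adjusted over the list alone, from 95.1 ± 21.6 to 312 ± 98.1 CPM, beside 0 over all genes tested with edgeR. Fatty acid oxidation genes (21 genes; median -0.08, or -0.42 under library totals; adjusted p = 0.572) and circadian clock genes (28 genes; median 0.13, turning to -0.10 under library totals; adjusted p = 0.824) did not pass.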

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

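The tests of depth, neutrophil transcripts, exchanged labels and a wrong label of fever-1 were chosen only after the result was seen. Within each group, a library was singled out where its gap to the nearest other library, divided by the range of the group, was above Dixon's critical value for 4 samples. Of 260 groups of values 25 met this, and 16 of the 25 were values of fever-1. The number expected by chance, 13, would hold for values fixed before the data were seen. Some of the genes were named only after their values were seen, and values of the same library are not independent. The excess over 13 and the share of fever-1 therefore cannot be measured against chance, and the flagged values are given as descriptions.

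In fever-1 the first principal component score was 111.1, against -42.0 to -28.8 in the other fever libraries. Among heat shock genes, hsp90aa1.1 was at 185 CPM (23.9 to 28.5 in the other fever libraries), hsp70 MSTRG.19379 at 208 CPM (3.15 to 10.4), hsp70 MSTRG.19369 at 596 CPM (19.7 to 40.3) and bag3 at 23.6 CPM (0.461 to 1.46). Among myeloid and protease genes, mpx was at 2019 CPM (91.3 to 314), mmp9 at 5117 CPM (198 to 762) and ctsc at 546 CPM (308 to 327). The glycolysis gene gapdhs was at 12289 CPM (2127 to 2842) and the glucose transporter slc2a3b at 1262 CPM (136 to 254). casp3b was at 55.5 CPM (7.32 to 12.5), prdm1a at 528 CPM (109 to 126) and alas2 at 940 CPM (298 to 389). Centred list means of fever-1 were 1.48 for glycolysis (-0.394 to -0.127 in the other fever libraries), 0.83 for oxidative stress (-0.217 to -0.169) and -1.69 for the T cell list (0.212 to 0.406).

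The other results concerned other libraries. In ctrl-3, ENSONIG00000041748, described as an immunoglobulin light chain, was at 88.5 CPM (172 to 189 in the other ctrl libraries), hsp70 MSTRG.19379 at 19.7 CPM (1.98 to 3.59), and the centred mean of antigen processing and presentation at -0.622 (0.093 to 0.165). In ctrl-2, the CD8 alpha-like MSTRG.21162 was at 51.1 CPM (8.44 to 12.7). srebf1 was at 97.0 CPM in ctrl-1 (43.3 to 51.0 in the other ctrl libraries) and at 197 CPM in fever-4 (79.7 to 84.4 in the other fever libraries). ccne2 was at 4.14 CPM in fever-2 (7.503 to 7.774), ENSONIG00000038474, described as interferon-induced protein 44, at 2.79 CPM in fever-2 (0 to 0.092), and the granzyme K-like ENSONIG00000038802 at 145 CPM in fever-3 (0.086 to 4.48).

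The distance of ctrl-3 and fever-1 from the other libraries on the first component was weighed further. Sequencing depth was excluded, since fever-1 had 13.8 M counts and the other libraries 10.3 to 14.8 M. The position of ctrl-3 argues against an exchange of labels between ctrl-3 and fever-1. It was -0.07 on a scale from ctrl (0) to fever (1) set by genes ranked in the other 6 libraries. It does not exclude the exchange, since fever-1, a library labelled fever, lay at 0.24 on the same scale. The test written earlier for the exchange asked that both libraries lie on their own side and left it open, and it was replaced because an exchange needs both libraries out of place. A wrong label on fever-1 alone cannot be told apart from a fever sample in another state: its position was 0.24, as in ctrl libraries, but its second component score (-55.1, against 18.9 to 65.7 in ctrl) and its mean of the endoplasmic reticulum list (0.082, against -0.516 to -0.188 in ctrl) lay outside the ctrl range, on the side of fever. More neutrophil transcripts also stay open, since the centred neutrophil list mean was 1.29 in fever-1 but 0.21 in ctrl-3, where the highest other library had 0.16 and the SD of the other 6 was 0.28, and a different physiological state of fever-1 was not tested.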

How the results depend on the processing

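Sample quality weights, leaving out ctrl-3 and fever-1 together, list-alone counts, list members matched by RefSeq symbol or left out as misnamed, camera tests of KEGG pathways, Fisher tests on DESeq2 calls and the settings of the heavy chain share were chosen only after the result was seen. The endoplasmic reticulum and plasma cell lists passed camera in the scalings tried and with each library left out, and passed fry, but did not pass with an estimated correlation. For single named genes 1750 alternative values kept their direction and side of the threshold, 52 passed where the first did not, and 97 had the other sign. For called lists 162 kept the call, 35 lost it and 1 turned. The spread between libraries, not depth, limits the gene calls: simulated 4-fold changes were recovered at 4% with the dispersions of these libraries and at 95% with a dispersion of 0.05.

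edgeR called 0 genes under each scaling and filter, limma-voom and limma-trend called 0, and edgeR with the replicate number as a block called 0 (smallest adjusted p 0.788, 719 at an unadjusted p under 0.05). Calls were made by DESeq2 (195, of which 161 at least 2-fold), with sample quality weights (87 and 80), without both ctrl-3 and fever-1 (9 and 9), by DESeq2 without both (340 and 302), and over single libraries left out the count ranged from 0 to 18, with and without the 2-fold threshold. The genes shared with the 195 were 75 under quality weights, 8 without both and 17 without fever-1. The cause was not tested. Correlations of deviations from the group means gave no sign that replicate numbers pair the samples. They were -0.39, 0.17, -0.12 and -0.15, and no ctrl library correlated best with its own number. Since fever-1 and ctrl-3 lay far from their groups and weigh on these deviations, the correlations cannot exclude a pairing. The block left 12 lists passing.

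Of the lists, 11 passed camera, 0 with an estimated correlation and 3 by fry. For glycolysis the adjusted p over single libraries left out ranged from 0.00317 to 0.592, the latter turned without fever-1, and it was 0.815 without ctrl-3 and fever-1. Adjusted over the list alone, the endoplasmic reticulum list had 0 genes under library totals, 0 on log2(FPKM + 1), 0 on log2(FPKM + 0.1) and 0 without an FPKM minimum, and 5 to 17 over single libraries left out. For KEGG pathways 48 passed, 0 with an estimated correlation, 23 without heavy chain genes, 28 without ctrl-3 and fever-1, and 41 to 61 over single libraries left out. The Fisher test on edgeR calls gave 0 pathways, also at an adjusted p under 0.01, at 2-fold and with 5 to 500 members, since 0 genes were called (1185 at an unadjusted p under 0.05), and on DESeq2 calls it gave 28, or 3 without heavy chain genes. The log2 difference of the heavy chain share was -1.03 without its most abundant gene, 1.45 without both most abundant genes, and 1.87 to 2.58 over single libraries left out.

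Log2 changes with the other sign were as follows, each for a gene that did not pass the edgeR test, and the cause was not tested. Under library totals, HSPA8 had -0.01, hsp90ab1 -0.29, cirbpb -0.11, casp9 -0.13, mcl1b -0.05, tbx21 -0.09 and csf1ra -0.18. On log2(FPKM + 1) with and without the minimum, HSPA8 had -0.02, hsp90ab1 -0.28, cirbpb -0.11, casp3b -0.28, casp9 -0.17, tbx21 -0.08, csf1ra -0.15 and cd4-1 0.04. On log2(FPKM + 0.1) these were -0.02, -0.28, -0.11, -0.32, -0.18, -0.08, -0.17 and 0.06, and ENSONIG00000038802 had -0.17. hsp90ab1, with 0.01 at first, had -0.01 with median-of-ratios scaling, -0.05 with upper-quartile scaling, 0 with no filter, -0.01 with the stricter filter, -0.01 with DESeq2 and 0 with limma-voom and with the block. With limma-voom casp3b had -0.05, ddit3 0.16, ENSONIG00000037711 0.10, ENSONIG00000039404 0.07, cd4-1 0.33 and ENSONIG00000038802 -0.16, and with the block casp3b had -0.13, ddit3 0.27, ENSONIG00000037711 0.11, ENSONIG00000039404 0.08 and cd4-1 0.33. With quality weights hsp90ab1 had -0.17, casp3b -0.60, ddit3 0.31, zap70 0.03, cd4-1 0.01, bag3 -0.70 and mmp9 -0.34. Without ctrl-3 and fever-1, hsp90ab1 had -0.09, casp3b -0.67, casp3a 0.04, casp9 -0.08 and bag3 -0.88.

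Over single libraries left out, the lowest and highest log2 changes were -0.04 and 2.11 for hsp90aa1.1, -0.14 and 0.09 for hsp90ab1, -0.69 and 0.65 for casp3b, -0.17 and 0.26 for casp9, -0.05 and 0.49 for mcl1b, -0.10 and 0.36 for tbx21, -0.19 and 0.32 for csf1ra, and -1.89 and 0.79 for mpx. They were -0.48 and 0.56 for ddit3, -0.69 and 0.05 for ENSONIG00000037711, -0.68 and 0.05 for ENSONIG00000039404, -0.37 and 0.15 for zap70, -0.35 and 0.39 for cd4-1, -0.84 and 3.49 for ENSONIG00000038802, and -0.22 and 0.01 for ENSONIG00000015679. For hsp70 MSTRG.19369 they were -0.62 and 2.52, for bag3 -0.69 and 2.47, for gapdhs -0.03 and 1.20 and for mmp9 -0.09 and 2.30. The lowest values of hsp90aa1.1, hsp90ab1, casp3b, casp9, mpx, MSTRG.19369, bag3, gapdhs and mmp9 were those without fever-1.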

Other observations

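The camera tests of KEGG pathways, the Fisher tests on DESeq2 calls and the tests of antibody-secreting cells and of T cell numbers were chosen only after the result was seen, while the counts over splits of the libraries and the test of dilution were set before their results were seen.

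KEGG pathways of the secretory route were among those higher in fever by camera with its preset correlation. Protein processing in endoplasmic reticulum (177 tested genes) had a median log2 change of 0.33 and a camera adjusted p of 3.26e-10, N-Glycan biosynthesis (50 genes), which builds the sugar chains of secreted proteins, 0.44 and 1.61e-07, and Protein export (23 genes), which moves proteins into that compartment, 0.47 and 1.61e-07. Adjusted p values with an estimated correlation were 0.338, 0.683 and 0.997. SEC61A1 (ENSONIG00000020330), the channel through which secreted proteins enter, measured 172 ± 13.6 CPM in ctrl and 382 ± 78.2 CPM in fever (SD, n = 4). Pathways that were lower included Fanconi anemia pathway (49 genes; median -0.43; adjusted p = 1.21e-07; adjusted p = 0.997 with an estimated correlation) and DNA replication (39 genes; median -0.47; adjusted p = 2.43e-05; adjusted p = 0.997 with an estimated correlation). In all, 48 of 319 pathways passed camera, 40 higher and 8 lower, and 0 with an estimated correlation. Without heavy chain genes 23 passed, and without ctrl-3 and fever-1 28 passed. Among genes called by DESeq2, Fisher's exact test found 28 pathways, all higher, led by Protein processing in endoplasmic reticulum with 23 of 185 members called (adjusted p = 5.47e-17) and Protein export with 6 of 24 (adjusted p = 3.3e-05), against 64 called among 6260 annotated genes. Without heavy chain genes 3 pathways were left, Protein processing in endoplasmic reticulum (adjusted p = 1.16e-18), Protein export (1.42e-05) and N-Glycan biosynthesis (0.0169).

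The higher share of immunoglobulin heavy chain counts in fever was set against a technical explanation. Dilution by fewer red cell transcripts would raise markers of all other cell types alike, but their median unscaled log2 change was -0.1 (109 markers, quartiles -0.52 to 0.34) against 2.19 for the heavy chains, which excludes it. Reads moving between near-identical heavy chain genes were not tested: they would leave the sum over the family as it is, and they stay open for its single members. More antibody-secreting cells or more antibody transcripts per cell stay open as an explanation. The mean of the plasma cell list, which holds no heavy chain gene, differed in the direction this needs (exact permutation p = 0.0286, the smallest possible). The nearest libraries were fever-1 at -0.041 and ctrl-2 at -0.092. The list had already passed camera as higher in the same libraries, so this p adds no separate evidence. That list shares xbp1 with the endoplasmic reticulum list. Whether the number of cells or the output per cell differed was not tested. The shares argue against a state of fever-1 unlike the others as the cause. It had 1.97%, the lowest fever share, while the other fever libraries had 3.25 to 4.05% and the ctrl libraries 0.345 to 1.51%.

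Transcripts of CD3e, which is not in the T cell list, and of 3 CD8 alpha-like genes, which are, chosen after their values were seen, summed to 65.1, 70.8, 16.3 and 27.7 CPM in ctrl-1 to ctrl-4 and to 5.7, 8.5, 7.6 and 8.1 CPM in fever-1 to fever-4. Their median log2 change was -2.16. Fewer T cells in the fever samples would lower the other 25 genes of the T cell list by about as much, but their median was -0.1 (quartiles -0.31 to 0.11), which excludes a loss of that size as the whole cause. A smaller loss, or a loss of one kind of T cell, was not tested.

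The 35 splits of the 8 libraries into 4 and 4 were ranked for the 11 lists that passed camera, without correction for their number. For the endoplasmic reticulum list, only the real split gave as many as 14 genes adjusted over the list alone (highest other 10). Only the real split gave that list a camera p as small as 2.52e-13 (smallest other 2.64e-09). For the plasma cell list, only the real split gave a camera p as small as 9.49e-05 (smallest other 0.00073). A single split of 35 is the smallest share possible, and the lists were chosen because they passed in the real split. These ranks alone therefore do not exclude chance for either list. With an estimated correlation neither list passed camera (adjusted p = 0.203 and 0.276). Chance could not be excluded for the other called lists either. For cholesterol and fatty acid synthesis 2 splits gave a p as small as the real 0.00426 (smallest other 0.00345), for ribosomal proteins 3 (1.64e-18; 7.25e-29) and for B cell markers 4 (0.00115; 1.16e-05). For the cell cycle list it was 7 splits (1.4e-14; 7.81e-36), for oxidative phosphorylation 10 (5.34e-10; 1.81e-25) and for erythroid markers 13 (0.00103; 7.85e-21). For the Ras-Raf cascade and immediate early genes it was 15 splits (0.0104; 1.17e-07), for the proteasome 18 (0.00657; 1.36e-16) and for glycolysis 24 (0.00628; 4.05e-09).

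For edgeR the real split gave 0 genes (highest other 1), with or without the 2-fold threshold, beside 1185 genes at an unadjusted p under 0.05 and 195 by DESeq2. All 35 splits give at least 0, so that count says nothing about chance. Chance could not be excluded for the other counts over all genes. For DESeq2 4 splits gave as many as 195 genes (highest other 844), and for genes whose groups do not overlap 4 splits gave as many as 818 (highest other 1600). The 2.86% by chance is an average over splits, and single splits gave 67 to 1600 such genes. For lists passing camera 17 splits gave as many as 11 (highest other 18), and for KEGG pathways 23 gave as many as 48 (highest other 169). A split that parts ctrl-1, fever-2, fever-3 and fever-4 from the other libraries gave the 844 genes, and 1598 genes without overlap. It is the real split with ctrl-1 and fever-1 exchanged. These 4 libraries also had the lowest first component scores (-57.6 to -28.8, against -19.5 to 111.1 in the others). The 844 genes thus point to a structure of the samples that does not follow the groups. With ctrl-1 and fever-1 both left out of the ranking, their positions between ctrl (0) and fever (1) were 0.23 and 0.25. An exchange of their labels was not tested.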
